A study of Homo sapiens with 6 samples.

How the data were processed

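Gene expression was measured by RNA sequencing in A549 cells, a human lung adenocarcinoma line, transfected with SNHG5 or with a vector. There were 3 libraries per group, described in the labels as biological replicates. The labels' protocols name a silica-column RNA extraction and Illumina's TruSeq RNA kit with paired-end libraries, a kit that does not mark the strand. Reads of a gene and of an antisense or overlapping partner can therefore not be told apart with certainty, and near-identical copies such as IFNL2 and IFNL3, and many ribosomal protein genes with pseudogenes, are reported as uncertain.

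Per the submitters' processing notes, FastQC, HISAT2 and the GRCh38 build were used, with no versions named. The counting program, its handling of overlapping genes and its strand setting are not given in the sources used here. The authors deposited whole-number counts per gene and FPKM values side by side for each library, over 58302 gene rows, of which 28667 had a count in any library. The FPKM values deposited by the authors were the count divided by the library total and by a gene length. Among 12867 genes with at least 20 counts in every library, the length worked out from count and FPKM was the same in all libraries for 100% of genes, within 0.01%, and equalled the sum of a gene's distinct annotated exons for 92.1%. That length was a median of 1.52 times the union of exons, so the FPKM values understate levels of genes with many isoforms and were not used for any test. Identifiers were matched to GENCODE release 29, where 99.5% were found, 97.6% of those at the same position and 100% with the same symbol. Coordinates are those of the deposited table, on GRCh38.

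Library totals ran from 13378079 to 16999604 counts, so that 3 counts, taken as the floor for a gene not seen, corresponded to 0.176 to 0.224 CPM, the count scaled to a common library total. Floors cover counting error only. Replicates were compared by a chi-square of their counts, which gave 26.2 to 94.5 per degree of freedom within the groups, far above sampling noise, and each library was counted as 1 replicate.

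The counts were tested with edgeR 4.0.16 in R 4.3.3, using TMM factors, the filterByExpr minimum and the robust quasi-likelihood test, which left 15631 genes. All tests were two-sided with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. The standard error of a log2 fold change is its size divided by the square root of the quasi-likelihood F statistic. CPM values use the TMM-scaled totals. The common biological coefficient of variation was 30.8%. The 28 gene lists were tested with camera from limma 3.58.1 at a preset correlation of 0.01, and beside it with an estimated correlation and with fry. List medians per library are medians of log2 CPM, with a prior count of 2, as deviations from each gene's mean. Single values of 3 libraries against 3 were compared with an exact permutation test that ignores the replicate numbers, whose smallest two-sided p is 0.1.

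The groups, the main test, the gene lists, the rule for naming genes and the alternatives, except those said to have been added later, were fixed before the data were examined. The rule took SNHG5, then up to 10 genes per direction with the largest change past the threshold, non-overlapping groups and a mean log2 CPM of at least 2. With fewer than 5 such genes it took the 5 with the smallest p in that direction. It left out clone-named genes and pseudogenes, added up to 4 members of each list past the threshold, and added 11 markers of epithelial-mesenchymal transition whatever their values. Of the genes that the rule takes, 1 is not reported here. Genes named outside it are said to have been chosen after their values were seen.

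The groups share replicate numbers. Deviations from the group means correlated between same-numbered libraries at 0.35 for replicate 1, 0.16 for replicate 2 and 0.29 for replicate 3, while the other combinations ran from -0.34 to 0.12. By the rule that every such correlation exceed 0.1, the numbers were taken to pair the libraries. The labels' protocol also speaks of pairs of transfected cultures. Values with the replicate number as a block are given where they changed a call or a count. Its coefficient of variation was 26.2%.

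The edgeR step was tested on simulated counts of 15331 genes drawn from these libraries' means and totals, in 3 runs with 200 genes changed. It recovered 14.7% of 2-fold, 86.7% of 4-fold, 97.3% of 8-fold and 98.7% of 16-fold changes, with 8.2% of calls false. Changes of about 2-fold were therefore mostly out of reach in this comparison. The simulated genes varied independently and gave 486 calls over the 3 runs, against 20 in the data. The recovered shares may therefore be too high for the data.

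Alternatives were the replicate block, leaving out each library, other size factors, no filter and a stricter filter, DESeq2 1.42.0, limma-voom, fold minimums, and other forms of the list test. An alternative without a pair of libraries, the block together with an estimated correlation, and the interferon list as a result of its own were added after the data were seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.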

Results

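The transcriptomes of 6 A549 libraries were compared, 3 from cells transfected with SNHG5 and 3 from cells transfected with vector. SNHG5, the small nucleolar RNA host gene 5, is a long non-coding RNA, and the series title places it in migration, invasion and epithelial-mesenchymal transition (EMT) of lung adenocarcinoma cells. The libraries held 16634754, 13378079 and 16823958 counts in overexpression replicates 1, 2 and 3, and 15490294, 14798193 and 16999604 in control replicates 1, 2 and 3. No untransfected library was analysed here.

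The overexpressed gene itself did not separate the groups. SNHG5 (ENSG00000203875, chromosome 6, 85660950 to 85678736, minus strand, 23 annotated transcripts) stood at 114 ± 46.4 CPM in the libraries labelled overexpression and 72.5 ± 25.1 CPM in the libraries labelled control (SD, n = 3 each). The libraries labelled overexpression 1 and 2 held 153.3 and 126.5 CPM. The library labelled overexpression 3 held 62.9 CPM, next to 61.0 CPM in control 1 and 55.1 CPM in control 3, and below the 101.3 CPM of control 2. The log2 difference was 0.66 (SE 0.37), or 1.58-fold, with an edgeR quasi-likelihood adjusted p of 0.746 and an exact permutation p of 0.2 on log2 CPM, where 0.1 is the smallest possible. SNHG5 was higher in 3 of 3 same-numbered pairs, by 1.33, 0.32 and 0.19 on the log2 scale. Every direction below is thus between libraries as labelled, 1 of which, overexpression 3, held less SNHG5 than the mean of the controls.

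**Figure D1:**
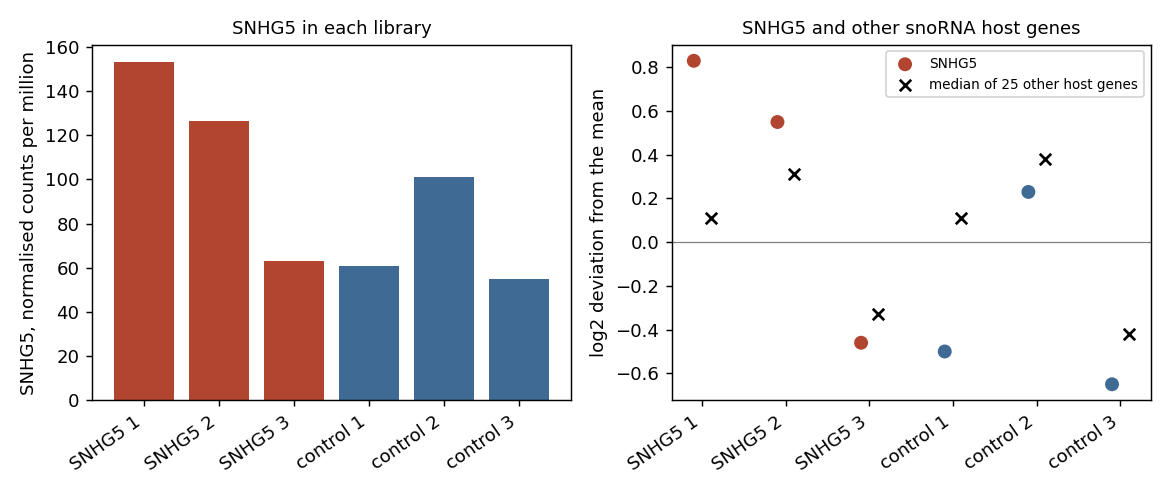
SNHG5 in normalised CPM per library (left), and its log2 deviation from the 6-library mean beside the median deviation of 25 other small nucleolar RNA host genes (right, crosses), with overexpression libraries in red and controls in blue. Overexpression 3 lies at 62.9 CPM, below control 2 at 101.3 CPM.

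Interferon-stimulated genes, the antiviral genes switched on by interferon signalling, were lower as a list in the libraries labelled overexpression by camera with the preset correlation (adjusted p 2.21e-53), though not with an estimated one (adjusted p = 0.35 with an estimated correlation, and 0.609 with the block as well). All 44 listed genes were measured and all 44 had a lower fitted level, with a median log2 fold change of -2.26, and 6 of them passed the edgeR threshold over all genes tested. RSAD2, which encodes the antiviral enzyme viperin, stood at 14.7 ± 3.12 CPM against 111 ± 3.00 CPM in the controls (7.54-fold lower, SD, n = 3 each). IFIT2, an interferon-induced RNA-binding protein, stood at 195 ± 64.9 against 1880 ± 645 CPM, and ISG20, an exonuclease, at 13.6 ± 1.19 against 110 ± 47.0 CPM. The list median per library was -1.16, -1.76 and -0.39 in overexpression 1, 2 and 3, and 1.00, 1.06 and 1.39 in controls 1, 2 and 3. Ribosomal RNA genes, mitochondrial ones and pseudogenes included, took 1.14%, 1.04% and 1.12% of the counts in overexpression 1, 2 and 3 and 0.85%, 0.8% and 0.84% in controls 1, 2 and 3, so that this share separated the same groups.

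Adjusted over the list alone, 42 of these 44 genes passed. With the replicate block the counts were 22 over all genes and 44 adjusted over the list alone. The members moved together, with an estimated correlation coefficient of 0.42. The self-contained fry test gave an adjusted p of 0.0375. The group difference of the list median was -2.25 with an exact permutation p of 0.1, the smallest possible for this test, which ignores the pairs.

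**Figure D2:**
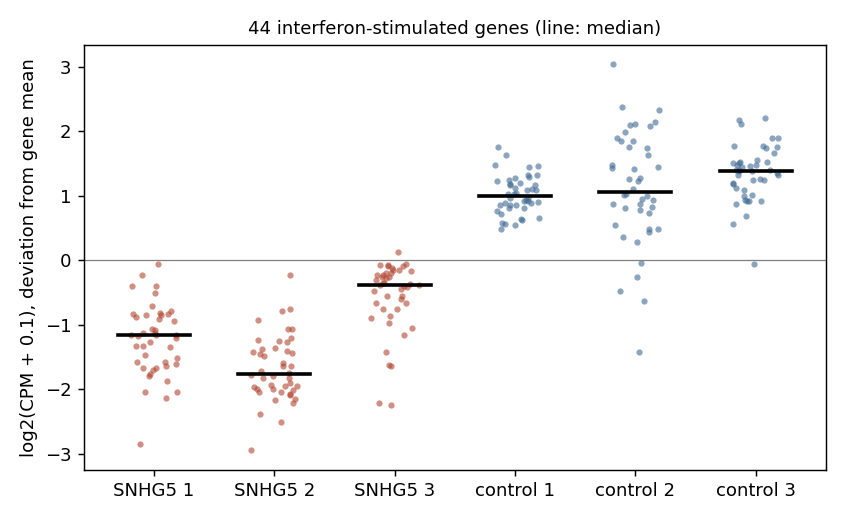
Deviation of log2(CPM + 0.1) from each gene's mean over 6 libraries for the 44 interferon-stimulated genes, 1 point per gene, with black lines at the library medians. The overexpression medians lie between -1.76 and -0.39 and the control medians between 1.00 and 1.39.

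Among all 15631 genes, 16 were lower and 4 higher in the libraries labelled overexpression. The interferon genes themselves were among the lower ones. IFNL1, IFNL2 and IFNL3, which encode type III interferons, were 9.14-fold, 13.3-fold and 12.1-fold lower, although IFNL2 and IFNL3 are near-identical and may share reads. LAMP3, a lysosomal membrane protein and a marker of alveolar type 2 cells, showed the largest fall of the 16, from 43.0 ± 14.3 to 2.30 ± 1.13 CPM (18.4-fold). RET, a receptor tyrosine kinase, fell from 12.2 ± 2.49 to 0.873 ± 0.252 CPM (13.8-fold), and LMO2, a transcriptional cofactor, from 8.66 ± 1.99 to 0.636 ± 0.409 CPM (13.3-fold). TRIM22, an interferon-induced ubiquitin ligase, was 8.63-fold lower and PIK3AP1, an adaptor of phosphoinositide 3-kinase, 7.55-fold lower. Chosen after their values were seen, the remaining 5 lower genes were HLA-B and HLA-E, which present antigen, OASL, RASGRP3 and ATP10A, lower by 6.11-fold, 3.33-fold, 7.14-fold, 5.36-fold and 3.24-fold. IFNL1, TRIM22 and OASL are, with RSAD2, IFIT2 and ISG20, the 6 interferon list members already counted above.

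The higher genes were few. MSRB3, a methionine sulfoxide reductase (chromosome 12, 65278643 to 65488244), stood at 81.1 ± 13.2 CPM against 8.98 ± 2.01 CPM in the controls, 9.02-fold higher, with an edgeR quasi-likelihood adjusted p of 0.0123. ZNF518A, a zinc finger protein, was 5.41-fold higher (78.3 ± 23.0 against 14.5 ± 2.77 CPM) and MRFAP1 3.47-fold higher (247 ± 15.1 against 71.1 ± 7.19 CPM). The rule also names RNF146, a ubiquitin ligase of the Wnt pathway, and CBWD5, which did not pass, at 3.44-fold and 2.92-fold with edgeR adjusted p of 0.0668 and 0.0873. AC120057.2 (ENSG00000262526, chromosome 17, 7240427 to 7244635), named after its values were seen, had 897, 363 and 313 counts in overexpression 1, 2 and 3 and 0 in every control, at least 170-fold higher than a floor of 3 counts per control library. AC120057.2 overlaps GABARAP on the same strand. GABARAP stood at 30.7 ± 0.387 CPM in the overexpression libraries against 78.9 ± 37.6 CPM in the controls (edgeR adjusted p 0.282). Also chosen after their values were seen, 2 more genes overlap AC120057.2. CTDNEP1 lies on the same strand (76.8 ± 4.51 against 71.4 ± 7.08 CPM), and AC120057.3, which was not tested, on the opposite one. The counts of AC120057.2 thus depend on how the authors assigned shared reads.

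The 20 genes had edgeR quasi-likelihood adjusted p between 0.0123 and 0.048. With the replicate block 4 genes were higher and 69 lower, the 20 among them. The count depended on single libraries. Leaving out overexpression 2, control 2 or control 3 left 0 genes past the edgeR threshold, and leaving out overexpression 1 left 1. In the fits with 0 genes, 635, 871 and 742 of 16042, 16044 and 16018 genes tested had an unadjusted edgeR p under 0.05. These counts lie near or below the share of 0.05 that is reached without any difference. Leaving out overexpression 3 gave 20 higher and 144 lower genes, and leaving out control 1 gave 3 higher and 19 lower, 15 of the 20 among them. All 20 genes kept their sign in each of these 6 fits. Log2 fold changes ran from 3.03 to 3.37 for MSRB3 and from -4.63 to -3.92 for LAMP3. For each of the 20, all libraries of 1 group lay above all of the other. Leaving out 1 library could hardly turn a sign, so the kept signs are no separate support.

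**Figure D3:**
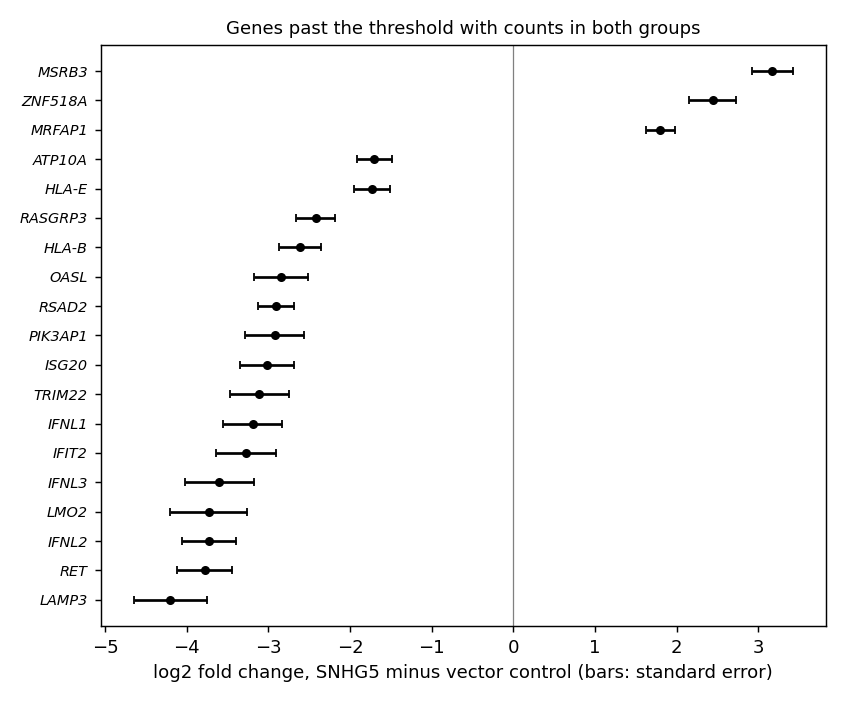
Log2 fold change (SNHG5 minus vector control) with its standard error for the 19 genes past the threshold that had counts in both groups. Values run from -4.20 for LAMP3 to 3.17 for MSRB3.

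EMT markers, the subject of the series title, did not pass the threshold. CDH1, which encodes E-cadherin, stood at 14.8 ± 11.4 CPM in the overexpression libraries and 26.9 ± 8.65 CPM in the controls, a log2 difference of -0.86 (SE 0.52, edgeR adjusted p 0.746). VIM (vimentin) and CDH2 (N-cadherin) had log2 differences of 0.01 (SE 0.24) and -0.21 (SE 0.22), and FN1 (fibronectin) -0.46 (SE 0.27). Of the transcription factors that drive EMT, SNAI1 was at -0.65, SNAI2 at -0.01, ZEB1 at 0.85, ZEB2 at 0.12 and TWIST1 at -0.35, all with edgeR adjusted p of 0.746 or more. MMP2, a matrix protease, was at -0.24, turning to 0.14 without overexpression 1 and lying at -1.37 without overexpression 3, where CDH1 was at -1.71 and SNAI1 at -1.67. ZEB2 ran from -0.29 to 0.53, SNAI2 from -0.29 to 0.22 and VIM from -0.12 to 0.15 over the fits without 1 library. MMP9 had 13 counts over 6 libraries, too few to test.

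The EMT lists were 25 epithelial junction and keratin genes, 32 mesenchymal genes and 16 EMT transcription factors with median log2 fold changes of -0.18, -0.23 and -0.31. None of their members passed in edgeR over all genes, and 2, 1 and 3 had an unadjusted p under 0.05. limma-voom called 0 members of each, while DESeq2 called 1 mesenchymal gene as higher and 1 EMT transcription factor as lower. Adjusted over the list alone, 1 EMT transcription factor was lower, and 2 with the block. The camera adjusted p of the lists were 0.165, 0.0638 and 0.0638, and with the replicate block 0.219, 0.0131 and 0.0476. The fry adjusted p of the EMT transcription factors was 0.0375. None passed with an estimated correlation, at adjusted p = 0.609 for each with the block. Changes of 2-fold were recovered in 14.7% of simulated genes, so smaller changes in these markers were mostly not detectable with 3 libraries per group. Larger changes could be missed as well. Only 6 of 44 interferon-stimulated genes passed at a median log2 fold change of -2.26, and CDH1, SNAI1 and MMP2 had SEs of 0.52, 0.60 and 0.61.

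Of the other lists, 4 passed camera with the preset correlation, all lower in the libraries labelled overexpression. None of the 4 passed with an estimated correlation (adjusted p = 0.656 for the alveolar and airway markers, 0.795 for the ribosomal protein and NRF2 target genes, 0.584 for the Wnt targets). Alveolar type 2 and airway secretory markers had a median of -0.58 over 9 tested genes (camera adjusted p 0.00392), with LAMP3 the 1 member past the threshold and FOXA1, AGR2 and FOXA2 at -0.84, -1.19 and -0.66. AGR2 held 247.7 CPM in control 2 against 37.8 to 72.7 CPM elsewhere and was at -0.22 without it, and in replicate pair 3 AGR2, FOXA2 and the list median lay at 0.04, 0.05 and 0.04. The 77 cytosolic ribosomal protein genes had a median of -0.30 (camera adjusted p 0.000453), RPS10 lying at -1.03, RPL12 at -0.61 and RPL17 at -0.53. Their list median per library was 0.65 in control 2 and between -0.21 and 0.04 in the other libraries, and the call was lost without control 2 and without overexpression 3 (6 and 9 lists then passed). The 12 Wnt target genes had a median of -0.40, RNF43 lying at -1.16, NKD2 at -0.67, MYC at -2.59 and NKD1 at -1.01. Over the fits without 1 library MYC ran from -3.98 to -1.91 and NKD1 from -1.82 to -0.63, and MYC was at -4.56, 2.47 and -4.43 in replicate pairs 1, 2 and 3. The 33 NRF2 target genes, of the oxidative stress response, had a median of -0.26, HMOX1 lying at -1.05, CBR3 at -1.33, CBR1 at -1.05 and GPX2 at -0.66. GPX2 held 84.6 CPM in control 2 against 24.9 to 30.1 CPM elsewhere and was at 0.15 without it, and CBR1 ran from -2.43 to -0.63 over the fits without 1 library. The Wnt and NRF2 lists both had a camera adjusted p of 0.0481. The Wnt call was lost without overexpression 2 or control 1 and the NRF2 call without overexpression 1 or control 2 (8, 6, 6 and 6 lists then passed). Both calls were also lost with the stricter filter, and the Wnt call with DESeq2.

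**Figure D4:**
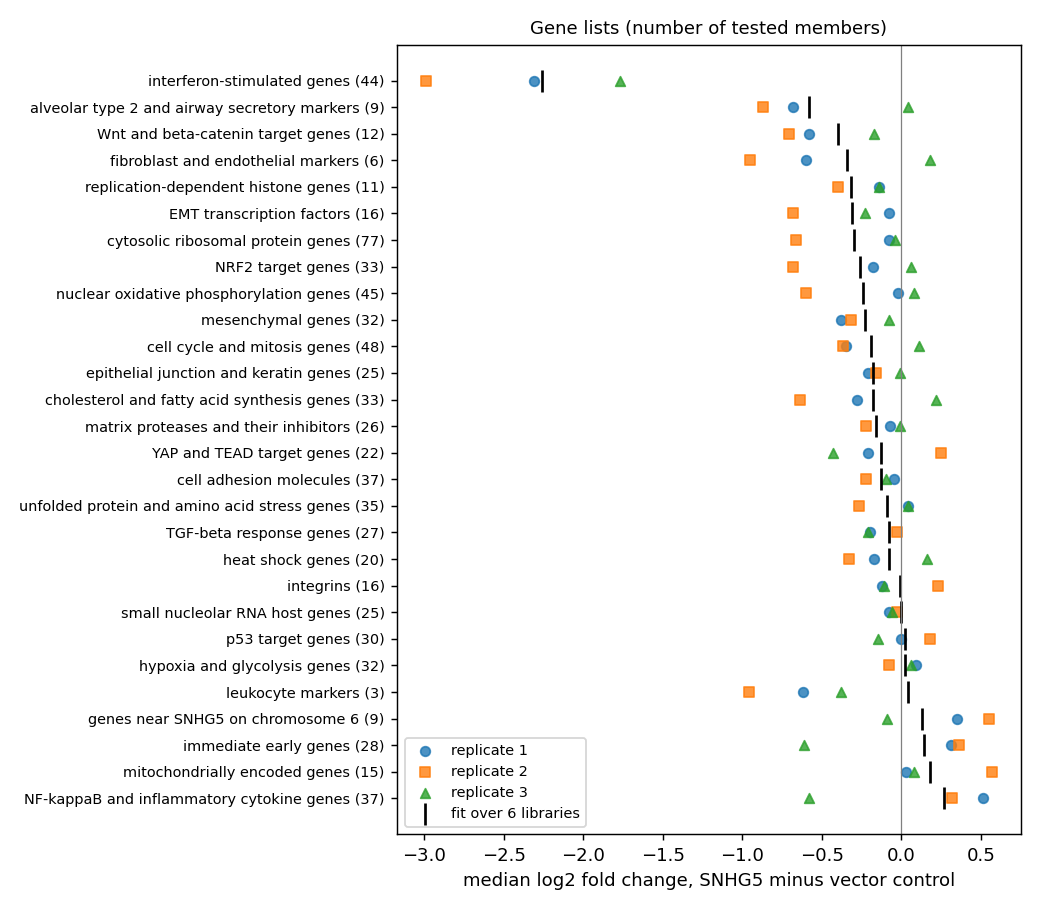
Median log2 fold change of each list's tested members, SNHG5 minus vector control, within each same-numbered pair (coloured symbols) and in the fit over 6 libraries (black bars). Interferon-stimulated genes lie at -2.31, -2.99 and -1.77 in replicates 1, 2 and 3, and the other fitted list medians between -0.58 and 0.27.

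Control 2 stood apart from the rest in RNA composition. MALAT1 and NEAT1, long nuclear RNAs, were at 28.9 and 24.1 CPM there, against at least 121.5 and 104.1 CPM in the other libraries, and mitochondrially encoded genes took 2.57% of its counts against 3.8% to 6.16%. The first principal component, with 46.4% of the variance, placed overexpression 1 and 2 at -63.7 and -48.7 and overexpression 3 at 25.2, next to control 3 at 30.5. Spearman correlation was 0.983 between overexpression 1 and 2, and 0.981 between overexpression 3 and control 3.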

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

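The alternatives without a pair of libraries and with both the block and an estimated correlation were added after the data were seen, as was treating the interferon list as a result of its own. SNHG5 kept its direction in all 13 alternatives and stayed short of the threshold in 12 of them, with log2 differences of 0.39 to 0.97 without 1 library. It passed in the one without overexpression 3 and control 2 (1.26, edgeR adjusted p 0.0222), which is circular for SNHG5. The higher genes numbered 20 with DESeq2 in place of 4, and 0 to 20 over the fits without 1 library. The lower genes numbered 69 with the replicate block, 72 with no filter and 246 with DESeq2 in place of 16, and 0 to 144 without 1 library. All 20 genes were called by DESeq2, with no filter and with the block, and 19 by limma-voom. Without both libraries there were 114 higher and 388 lower genes. Those 2 libraries were picked by their measured SNHG5 level, so the values without them are biased towards a larger contrast and bear on no claim about SNHG5.

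The lists past the threshold numbered 5, against 10 with the replicate block, 10 with no filter, 3 with the stricter filter, 10 with camera on ranks, 3 with fry, 3 without the lists with near-identical members, 11 without those 2 libraries, and 6 to 9 without 1 library. With an estimated correlation camera called 0 lists, 1 having an unadjusted p under 0.05, and again 0 with the block. The interferon list kept its direction in all 18 alternatives, between -2.76 and -1.97. Other forms of the list test reuse the fold changes of their fit, and the library medians of the groups did not overlap. Most alternatives could therefore not have turned the direction. The list lost its call in 2 of them, camera with an estimated correlation (-2.26, adjusted p 0.35) and with that and the replicate block (-2.40, adjusted p 0.609). There, members moving together widen the test. Causes of the other shifts were not tested. Adjusted over the list alone, NRF2 target genes had 1 lower member with the block and 0 without. The block changed no other call than these and those given. Of 492 results for 41 other named genes, 425 stayed on their side of the threshold, 59 lost a call, 8 gained one and 0 called genes reversed. In 14 of the 425 the uncalled genes ZEB2, VIM, MMP2, SNAI2 or GPX2 turned in sign. Depth set a floor of 0.176 to 0.224 CPM per library.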

Other observations

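Of the tests below, those of a swapped pair of libraries, of the other host genes, of SNHG5 reads split by gene and of GABARAP reads were chosen only after the result was seen. Chosen after their values were seen, genes upstream and downstream of interferon passed edgeR once the replicate block was used. IFNB1, which encodes interferon beta, stood at 1.49 ± 0.602 CPM in the libraries labelled overexpression and 13 ± 5.25 CPM in the controls (SD, n = 3, edgeR adjusted p 0.0312 with the block and 0.0667 without). IFIH1 and TLR3, sensors of double-stranded RNA, were 4.35-fold and 7.79-fold lower, and NLRC5, an activator of class I antigen presentation genes, 4.60-fold lower (edgeR adjusted p with the block 0.0304, 0.0367 and 0.0284). Of these, IFNB1 and IFIH1 are interferon list members and belong to the 22 already counted with the block.

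The remaining 20 lists had median log2 fold changes from -0.34 to 0.27 and camera adjusted p from 0.0585 upwards. With the block 3 of them passed, cholesterol and fatty acid synthesis genes (-0.18), mitochondrially encoded genes (0.18) and nuclear oxidative phosphorylation genes (-0.24), with camera adjusted p of 0.0296, 0.0218 and 0.0388. Replicate pair 2 differed most, with list medians of -0.28, -0.64 and 0.22 in pairs 1, 2 and 3 for cholesterol synthesis, 0.03, 0.57 and 0.08 for mitochondrially encoded and -0.02, -0.60 and 0.08 for oxidative phosphorylation genes, and control 2 had library medians of -1.08 for the mitochondrially encoded and 0.59 for the oxidative phosphorylation genes. None of the 3 passed with the block and an estimated correlation (adjusted p = 0.778, 0.671 and 0.778). NF-kappaB and inflammatory cytokine genes had library medians of 0.55, 0.61 and -0.99 in overexpression 1, 2 and 3 and -0.03, 0.36 and -0.33 in controls 1, 2 and 3, and their list median (0.27) and camera direction (lower) differed in sign, as did those of the immediate early genes (0.14). CXCL8, an inflammatory chemokine chosen after its values were seen, held 1087.8, 1092.1 and 105.4 CPM in the overexpression libraries and 321.9, 561.9 and 207.2 CPM in the controls. MYC held 7.83, 39.9 and 5.76 CPM against 187, 7.08 and 127 CPM, so control 2 lay with the overexpression libraries for this gene. Leukocyte markers had 3 tested members of 20, a median of 0.04 and a fry adjusted p of 0.0375 for a lower level. Of the 3, CD68, a lysosomal protein abundant in macrophages, was at 34.5 ± 7.62 CPM in the overexpression libraries and 86.1 ± 9.49 CPM in the controls (edgeR adjusted p 0.0948, 0.00125 adjusted over the list alone), and CORO1A and ITGAM had log2 differences of 0.04 and 0.22.

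The lower interferon-stimulated genes were tested against 3 technical explanations. A single library does not account for them, since the list median stayed between -2.76 and -1.97 in all 6 fits without 1 library, where camera with the preset correlation gave adjusted p of at most 1.47e-34 (with all libraries, adjusted p = 0.35 with an estimated correlation). Length, GC content and expression do not either, since the list median of -2.26 lies outside -0.09 to 0.11, the central 95% of 10000 lists matched on these, and leukocytes in the vector cultures are argued against by PTPRC at 0 CPM in every vector library, as were LYZ and TYROBP, although CD68 was higher there. The real grouping called 20 genes, and the highest of the 9 other groupings into 3 and 3 called 1. With the block it called 73, and the highest of the 3 others that part the same-numbered pairs called 0. Each other grouping mixes libraries of both groups, so fewer calls there can follow from the difference itself and are no separate support. In addition, 10 and 4 groupings are too few for a share under 0.05. A lower response with SNHG5 and a response raised by the vector itself both remain as hypotheses, untested without untransfected cells, and the transfected material may also differ between the groups.

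The overlap of SNHG5 levels was tested against a swap of overexpression 3 with control 2 and against variation shared with other host genes. Of the 502 genes called without these 2 libraries 498 were also tested with all 6, and control 2 lay on its own side for 83.7% of them. That share alone cannot decide, since a library unlike overexpression 1 and 2 may fall on the control side whatever its label. Control 2 had an interferon list median of 1.06, against 1.00 and 1.39 in the other controls and -1.16 and -1.76 in overexpression 1 and 2. For these genes that argues against this swap, since a swap needs both libraries out of place. Overexpression 3 lay on its own side for 35.7% of the 498 genes. Both libraries did for 30.3% (61.5% of the 39 interferon list genes) and neither for 10.8%. The share for both fell short of a bound of 80% first set for both together and, after these values were seen, applied to each library. The 498 genes compare overexpression 1 and 2 with controls 1 and 3. Replicate 2 thus stood only on the overexpression side and replicate 3 only on the control side. A difference between replicate numbers can therefore place overexpression 3 with the controls, and control 2 with the overexpression libraries, whatever their labels. After subtracting the median of 25 other host genes, the lowest overexpression library exceeded the highest control by 0.02, against -0.69 before, a margin below the standard error of 0.19, so that shared variation cannot be told apart from a missing increase of SNHG5. A weak or lost overexpression in the culture of overexpression 3 may also give this overlap, as may a wrong label of that library alone. Neither was tested. Overexpression 3 held MSRB3 at 96.3 CPM, against at most 11.3 CPM in a control, and 313 counts of AC120057.2, against 0 in every control. All 20 called genes, both of these among them, were also called without overexpression 3, so their calls do not rest on its label. For both genes it lay with overexpression 1 and 2, while most of the 498 genes placed it with the controls.

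The higher genes were tested against reads shared with SNHG5, a local gain, and reads of an overlapping gene. SNHG5 reads are argued against for MRFAP1, ZNF518A and AC120057.2, of which 0 had a 31-base stretch in common with SNHG5 transcripts, and for MSRB3, which had 7 of its 7540 such words in common, by its levels: the lowest overexpression library exceeded the highest control by 61.4 CPM for MSRB3 (largest SD 13.2) and by -38.3 CPM for SNHG5. A gain of the surrounding regions is argued against by a median log2 fold change of -0.19 over 61 tested neighbours within 500 kb, below the random range of -0.12 to 0.13 and not inside it as had been predicted, although 42 of these lie near AC120057.2 and 1 near MSRB3. For AC120057.2 the sum with GABARAP was 85.4, 57.4 and 48.5 CPM in overexpression 1, 2 and 3 and 44.2, 118.9 and 73.7 CPM in the controls, a log2 difference of -0.24. The sums overlapped, as predicted for GABARAP reads counted as AC120057.2 in 1 group only. They cannot decide this, since the wide spread of GABARAP in the controls makes an overlap likely in either case. GABARAP was level at 30.9, 30.9 and 30.3 CPM in overexpression 1, 2 and 3, where AC120057.2 held 54.4, 26.4 and 18.2 CPM. The other 3 higher genes had no overlapping gene that was tested, and a response to SNHG5 stays among their open explanations. MSRB3, MRFAP1 and ZNF518A held 96.3, 264 and 51.8 CPM in overexpression 3, where SNHG5 was at 62.9 CPM. In control 2, with SNHG5 at 101.3 CPM, they held 8.13, 78.6 and 12.9 CPM. They thus did not follow the measured SNHG5 level in these libraries, although ZNF518A was lower in overexpression 3 than in overexpression 1 and 2.

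The number of lists past the camera threshold did not set the real grouping apart. It called 5 lists, 9 of the 10 groupings including the real one called at least as many, and the highest other called 14, while 10 groupings are too few for a share under 0.05. The median of the interferon list was 2.26 in size in the real grouping and at most 0.97 in the others. This list was singled out after the data were seen. Each other grouping mixes libraries of both groups, so a smaller median there follows from the difference itself and is no separate support.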
